A study of Drosophila melanogaster with 2 samples.

How the data were processed

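ChIP-seq with an anti-GFP antibody was carried out on whole adult female flies of a transgenic line expressing a CG1620-eGFP fusion. The labels give 2 biological replicates, numbered 2 and 3, from separate biosamples of 1 line, with chromatin sheared by sonication to a size range of 200 to 800 bp; a replicate 1 was not analysed here. Both replicates form 1 group. Since no other group exists, no test compares conditions, and the p-values cover the spread over peaks, genes or positions, not the spread between flies.

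The authors deposited lists of peaks, not reads. Per the file headers and the text files deposited beside them, each replicate has a list of candidate peaks and background made from its own alignments and 1 control file, a pooled list was made from both replicates together, and the optimal set was thresholded by IDR from these lists. All exist on the dm6 and dm3 builds. The aligner, peak caller, IDR threshold, versions and the treatment of reads that match several places are not given in the sources used here, and the control itself was not used here. The value of each peak is a signal value, a score of the authors' peak caller relative to the control, deposited without scaling between lists; it was used to rank and describe peaks within a list, and between lists only through ranks, correlation and the ratio named in the report. The summit is the deposited offset from the start of the peak. The column meant for a p-value holds no values. All lists on dm6 had 30000 candidates apart from the IDR set, and their weakest signals were 18.9 (pooled), 14.2 (replicate 2) and 6.69 (replicate 3), so each list stops at a rank and its weakest entries lie in background. The 3894 IDR peaks were the 3894 strongest of the pooled list, with a weakest signal of 70.0. The median peak width was 400 bp in the pooled list and replicate 2, and 370 bp in replicate 3. The precision of single signal values cannot be given, since the lists hold no read counts; intervals for shares are exact binomial (Clopper-Pearson, 95%) and cover counting error only.

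Coordinates are those of dm6, 1-based. Annotation was Ensembl release 115 and sequence the RefSeq assembly of the same release 6 genome: every peak end lay within its chromosome, and of 30593 annotated start codons 99.8% read ATG in the sequence. The dm3 lists (3550 IDR peaks) were used only for alternatives of the replicate overlap, the correlation and the X share; since no dm3 annotation was used here, the X share of the dm3 peaks was set against that of dm6 TSS positions; 3 dm3 IDR peaks lay outside the arms and chromosome 4. Exact duplicate lines were dropped. TSSs were the 5′ ends of annotated transcripts of 17896 genes, without pseudogenes and transposable elements, at 23307 distinct positions. A promoter peak has its summit within 500 bp of a TSS; other summits were assigned in the order coding sequence, 5′ UTR, 3′ UTR, intron or non-coding exon, intergenic.

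Replicate overlap compared as many of the strongest candidates as there were IDR peaks and required an overlap of at least 50% of either peak, with 1000 circular shifts within chromosomes (one-sided). Correlation used the strongest overlapping candidate of each replicate, with a Fisher interval for rho. Promoter share used 1000 circular shifts (two-sided), the X share an exact binomial test, and promoter signal a permutation test of medians with 100000 resamples. Gene lists were tested by Fisher's exact test with Benjamini-Hochberg adjustment over the lists of at least 5 members, protein-coding lists against other protein-coding genes and RNA genes against other non-coding genes. Odds ratios have 0.5 added to each count. Motifs, given as IUPAC codes and read on both strands, and all 6-mers were compared between the 50 bp either side of a summit and flanks of the same total length by an exact McNemar test over peaks, with Benjamini-Hochberg adjustment at 0.05. Matches were placed by their midpoint. In the comparison with unbound promoters, each unbound TSS was given the offset of a bound summit from its TSS, drawn at random (median -61 bp in both sets).

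The tests, the 24 gene lists, the 22 motifs and the alternatives were fixed before the data were examined, apart from the split of the X share by location, the tests of the CG1620 region, the head-to-head gene pairs, the odds ratios without cytoplasmic ribosomal proteins, and the comparisons of motifs and of G and C content between peaks by location or strength, which were chosen after results were seen. The test of the 7-mer AACCCCC and the pooled, stratified and weak-candidate odds ratios of the 6 lists were prompted by the data too; the bounds for the 7-mer and for the stratified and weak-candidate odds ratios were written before those values were seen. In the CG1620 region, promoter density was tested in 3 ways, each chosen after the one before had been seen: IDR peaks away from promoters, all IDR peaks, and the number of TSS positions. The rule for what is named was fixed before the data were examined. It named the 25 strongest IDR peaks with every gene with a TSS within 500 bp of the summit or else the nearest. CG1620 and up to 4 members of each gene list with the strongest promoter peak were named too. So were the 5 strongest candidates of each replicate without a partner in the other, and all motifs past the threshold. For 6-mers the rule named the 10 with the lowest p, and it was applied here only to those more frequent at summits. Genes in the CG1620 neighbourhood and the depleted 6-mer with the lowest p were named after their values were seen. Alternatives were the overlap rule (1 bp, 80% of both peaks, summits within 100 bp), the number of peaks, each replicate left out, the 1947 strongest IDR peaks, merging summits within 100 bp, promoter windows of 250 and 1000 bp, other backgrounds, the dm3 lists, TSS clusters counted once, and a motif window of 100 bp either side.

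The scripts were tested on simulated peaks. A planted promoter share of 40% was recovered as 40.0% above chance, a planted overlap of 70% as 70.4%, and a planted gene list and motif were called with 0 false lists and 0 false motifs. Both 6-mers inside the planted motif were called, as was 1 6-mer that shared no run of 5 bases with it. The simulated genes received peaks independently of their neighbours, and the simulated summits were random genomic positions. Observed summits lie mostly at promoters and differ in composition from their flanks. The simulation therefore does not give the rate of false lists, motifs or 6-mers in the observed data. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and statsmodels for the stratified odds ratio.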

Results

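Binding of the CG1620 protein was mapped by chromatin immunoprecipitation with sequencing (ChIP-seq) in whole adult female Drosophila melanogaster. The flies carried a transgene for CG1620 fused at its C-terminus to enhanced green fluorescent protein (eGFP), and chromatin was precipitated with an antibody against GFP. The labels class the experiment as a transcription factor ChIP-seq. There was 1 group with 2 biological replicates, which the labels number 2 and 3, and no second condition. The comparisons were therefore between the replicates, and between the peaks and the rest of the genome. Each replicate and the pooled data had a list of 30000 candidate peaks on the dm6 genome build. The irreproducible discovery rate (IDR) procedure, which sets from the agreement of ranks between replicates how many peaks to keep, left the authors with an optimal set of 3894 peaks, the strongest of the pooled list. These peaks covered 1425 kb, or 1.06% of the chromosome arms and chromosome 4. Sequencing depth is unknown, because the lists hold no read counts.

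The first comparison asked how far the replicates found the same sites. Of the 3894 strongest candidates of replicate 2, 2850 overlapped one of the 3894 strongest of replicate 3, a share of 73.2% (95% exact binomial interval 71.8 to 74.6%). Shifting the peaks of replicate 2 along their chromosomes gave a mean share of 1.14% and at most 1.72% (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). Of the IDR peaks, 3747 had a candidate in both replicates, and 147 lacked one in at least 1 of them. Across those 3747 peaks the signal values of the replicates had a Spearman's rho of 0.694 (95% interval 0.677 to 0.710) and a Pearson's r of 0.757 on the log2 scale. Peaks are not independent replicates, so no p-value is given. The interval treats peaks as independent, so it may be too narrow, and it does not cover the spread between flies. The signal of replicate 2 was a median of 2.77 times that of replicate 3. The interquartile range of the log2 ratio widened from 0.50 among the strongest 974 IDR peaks to 1.04 among the weakest 973. The signal values are the authors' own and were not scaled between lists, so the ratio is not a measure of binding.

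**Figure D1:**
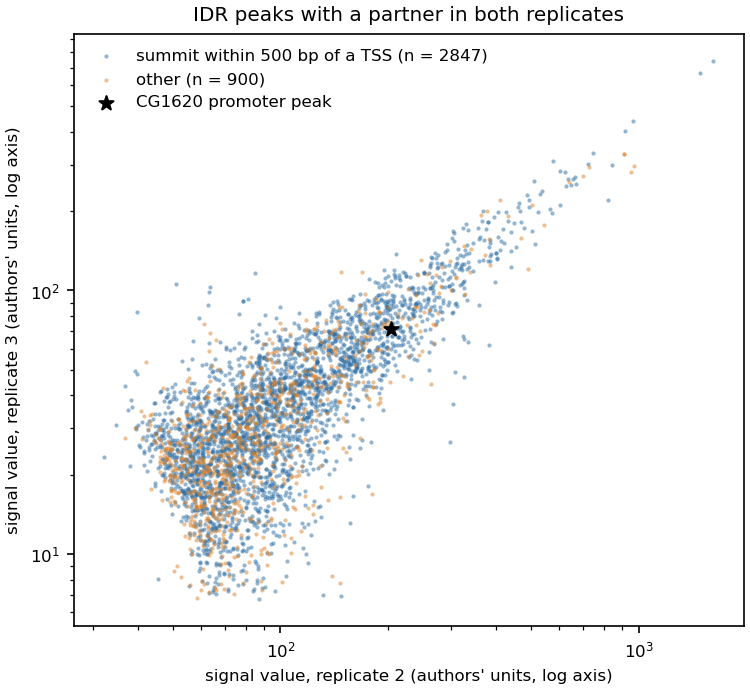
Signal value of each IDR peak in replicate 2 (x axis) and replicate 3 (y axis), in the authors' units on log axes, for the 3747 peaks with a candidate in both; blue points have their summit within 500 bp of a transcription start site and orange points do not. The points form 1 cloud that narrows towards strong peaks (rho = 0.694), and the star marks the CG1620 promoter peak at 203 and 71.7.

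Candidates seen in 1 replicate alone were common in the full lists and rare among strong peaks. Of the 30000 candidates of replicate 2, 49.6% overlapped no candidate of replicate 3, and in the other direction the share was 53.1%; among the 3894 strongest the numbers were 216 and 83. The strongest candidate of replicate 2 without a partner lay in Cat, the catalase gene (3L, 18822671 to 18823070), at rank 710 with a signal of 152. It was followed by candidates nearest to CG31751, whd, Sply and CG4935, at ranks 1115 to 1219. The candidate nearest to whd had its summit in asRNA:CR45134, 144 bp from the TSS. That nearest to CG4935 had its summit in crp, 7482 bp from the TSS. In replicate 3 the strongest without a partner was nearest to yem (3R, 29122789 to 29123158), at rank 1028 with a signal of 48.2, followed by those nearest to TfIIS, CG12535, Fis1 and CG43245, at ranks 1634 to 2243. The candidates nearest to CG12535 and CG43245 lay 1057 and 33134 bp from the TSS.

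The second comparison asked where in the genome the IDR peaks lay. The summits lay mostly at promoters: 2960 of 3894, or 76.0% (interval 74.6 to 77.3%), were within 500 bp of an annotated transcription start site (TSS), 5.68 times the mean of 13.4% for shifted peaks (permutation test, two-sided, p = 0.002, the smallest that 1000 shifts can give). Among the 3894 weakest candidates of the pooled list, the share was 18.8% (interval 17.6 to 20.1%). The median distance from a summit to the nearest TSS was 108 bp, and 79.9% of the promoter summits lay upstream of it; their median position was -61 bp relative to the TSS. In 41.1% of the promoter peaks, TSSs of at least 2 protein-coding genes lay within 500 bp of the summit, so a promoter peak often cannot be given to a single gene. In all, 3662 of 13945 protein-coding genes, or 26.3% (interval 25.5 to 27.0%), had a promoter peak.

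Away from promoters, summits in coding sequence were the rarest relative to shifted peaks. Only 17 summits, or 0.437%, lay in coding sequence against 14.0% of shifted peaks, and 23, or 0.591%, lay in 3′ untranslated regions (UTRs) against 4.52%. Introns and non-coding exons held 677 summits, or 17.4% against 40.4%, and intergenic sequence held 191, or 4.90% against 27.2% (permutation p = 0.002 for each of these classes). The 26 summits in 5′ UTRs outside promoter windows, 0.668%, did not pass against shifted peaks (0.610%, permutation p = 0.677). These are shares of all summits, so the 76.0% at promoters lowers the other classes as a group. The tests therefore do not show whether a class is scarce or common among the summits away from promoters. The ratio to shifted peaks was 0.0313 in coding sequence, 0.131 in 3′ UTRs, 0.181 in intergenic sequence, 0.431 in introns and non-coding exons, and 1.09 in 5′ UTRs. Promoter peaks had a median signal of 119 (interquartile range 89.5 to 185) and the other 934 peaks a median of 103 (81.5 to 147), a difference of 15.9 (permutation test over peaks, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Among the 1947 strongest IDR peaks the difference was 11.02, with a permutation p = 0.0546. Coding sequence held 1.69% of as many strongest candidates of replicate 3 alone.

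**Figure D2:**
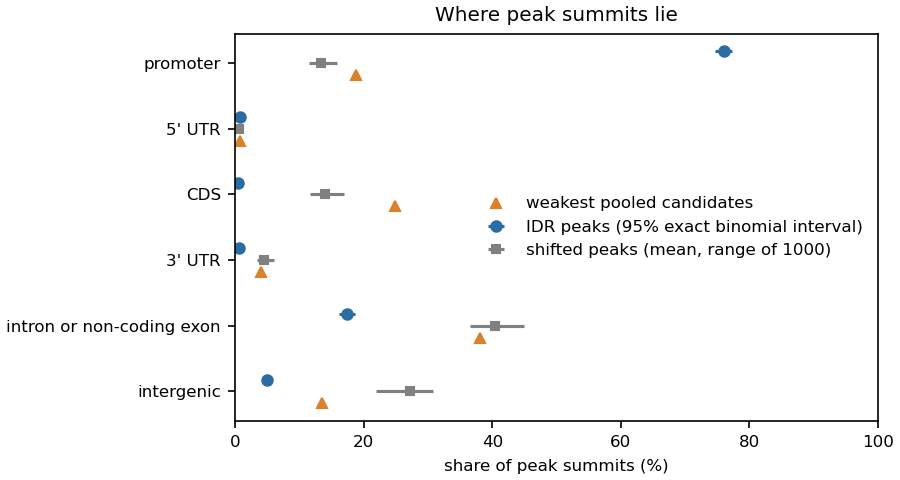
Share of peak summits (x axis, %) in each annotation class (y axis), with IDR peaks in blue (bars, 95% exact binomial interval), the mean and range of 1000 circular shifts in grey, and the weakest pooled candidates in orange. IDR peaks stand apart at promoters (76.0% against 13.4% for shifted peaks) and are scarcest in coding sequence (0.437%).

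The 25 strongest IDR peaks ranked high in both replicates: none ranked below 28 in replicate 2 or below 32 in replicate 3. They were chosen by the pooled signal, which was made from both replicates. High ranks in each replicate are therefore partly fixed by that choice. Of these peaks, 19 lay at promoters, 6 lay beyond, and 8 were on the X chromosome. The strongest had its summit at 19590623 on 3L, in intergenic sequence 99 bp from a TSS of CG14100, with a pooled signal of 2347 (replicate 2, 1616; replicate 3, 745). The next was on X at 2703890, 38 bp from a TSS of Ugalt, which encodes a UDP-galactose transporter, with a signal of 2151. The third lay on 2R at 15217754, 137 bp from the nearer TSS of mRpL41, a protein of the mitochondrial ribosome, and lncRNA:CR44463 (signal 1406). The fourth lay on 3L at 5139509, between CHMP2B, a subunit of the membrane-remodelling ESCRT-III complex, and Tcs5 (signal 1321). The strongest peaks beyond promoters were intronic or in non-coding exons: in CG11050 (2L, 6612709, signal 1268), in CG32772 (X, 4910370, signal 1232), in Tlk, which encodes the Tousled-like kinase (X, 3742229, signal 1230), in CG32486 (3L, 3060803, signal 1019, with CG16753 the nearest TSS at 5724 bp), in norpA, the phospholipase C of phototransduction (X, 4324994, signal 961), and in Lk6, which encodes a kinase (3R, 11761049, signal 897).

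The other 15 of the 25 strongest peaks lay at promoters with signals from 776 to 1139. They included the promoters of Gapdh2, a glycolytic enzyme (X, 15867991, signal 1034), of eIF6, a translation initiation factor, shared with asRNA:CR45928 (2R, 23850412, signal 1030), and of RpS27 and Nup37, a ribosomal protein and a nucleoporin that share a peak with sisRNA:CR46364 (3R, 25247526, signal 899). The transcription factor genes Sox14 (2R, 23978547, signal 820) and bbx (X, 21367841, signal 888) were also among them. The remaining promoter peaks in that set were at CG1888, lncRNA:CR44619, Sptr, lncRNA:CR31044 and GstE13, and at the gene pairs Shc and Atat, CG5611 and Mtl, Art3 and mRpS10, Pdrg1 and Pal1, and mRpL23 and CG9004. Gapdh2 ranked 9 in replicate 2 and 28 in replicate 3, and Art3 with mRpS10 ranked 24 and 7.

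CG1620, the gene whose product was tagged, lies on the minus strand of 2R from 7493806 to 7496466 and had an IDR peak at its own promoter. That peak ran from 7496169 to 7496568, with its summit at 7496369 in the 5′ UTR, 22 bp from a TSS. Its pooled signal of 275 ranked 406 of the 3894 IDR peaks; it ranked 371 in replicate 2 (signal 203) and 476 in replicate 3 (signal 71.7). Within 20 kb either side of the gene there were 9 IDR peaks, against a median of 2 around other protein-coding genes, and 99.2% of those windows held fewer. The group of peaks continued beyond this window on both sides. Another 4 lay 20 to 40 kb away towards lower coordinates and 6 towards higher coordinates. None lay from 40 to 60 kb on either side, so the group reached about as far on each side of the gene. The strongest of the 9 lay in the 5′ UTR of dpa, which encodes a subunit of the replicative helicase, at the promoter it shares with didum (summit 7500005, signal 435). The CG1620 promoter peak came next, then an intergenic peak 1607 bp from the nearest TSS (summit 7478769, signal 246). Peaks at the wech promoter (106) and within wech (94.1) followed. The promoter peaks of Coop (74.7), mEFTu2 (74.4) and az2, and that in asRNA:CR43723 (70.8), lay near the weakest IDR signal of 70.0. The Coop peak had no partner in replicate 3. The count of 9 therefore depends on the IDR cut-off, and the excess was not tested among stronger peaks alone. Weak candidates numbered 17 in this window against a median of 11.

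**Figure D3:**
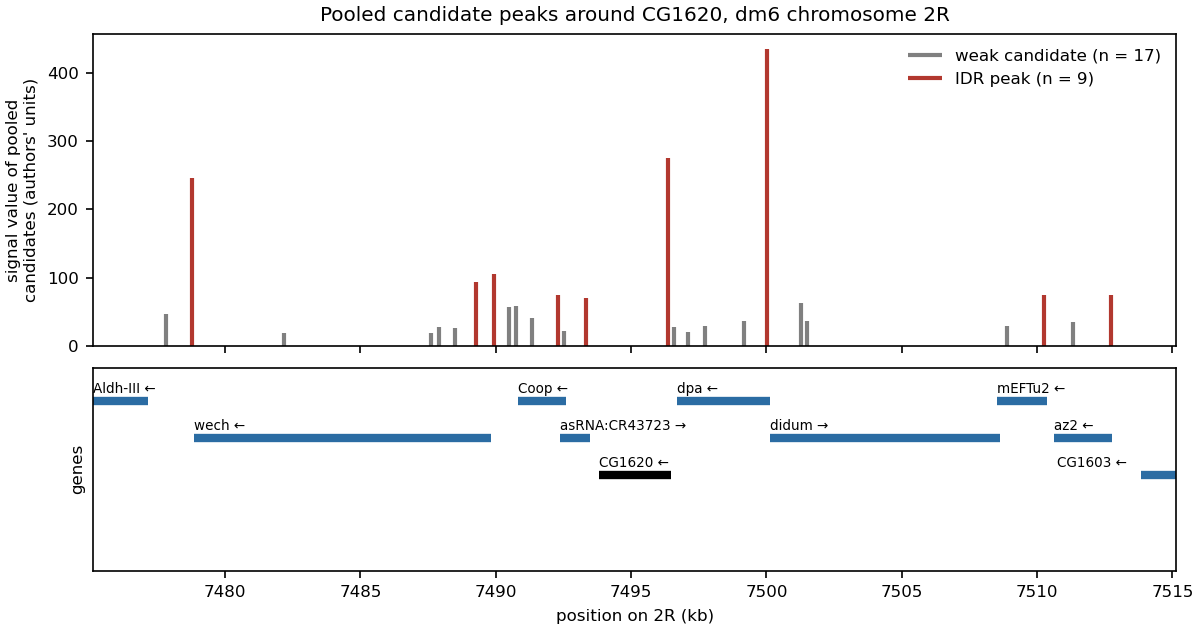
Pooled candidate peaks (vertical lines at the summit; y axis, signal value in the authors' units) within 20 kb either side of CG1620 on 2R (x axis, kb, dm6), with IDR peaks in red and weaker candidates in grey, above the annotated genes with their direction; genes reaching past the window are clipped. The 9 IDR peaks include the CG1620 promoter at 275 and the shared promoter of dpa and didum at 435.

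The third comparison asked whether the X chromosome, present in 2 copies in females, carried its share of peaks. It carried more: 846 of the 3867 IDR peaks on X, 2L, 2R, 3L and 3R were on X, or 21.9% (interval 20.6 to 23.2%), against 16.6% of annotated TSS positions (exact binomial test, two-sided, p = 1.09e-17) and 17.8% of the assembled length (p = 7.54e-11). Peak density was 35.9 per Mb on X and between 24.9 and 29.7 per Mb on the other 4 arms. Chromosome 4 had 27 peaks, or 20.03 per Mb. The median signal on X, 114, was close to the 114 to 118 of the other arms, and 69.7% of X peaks were at promoters, against 76.4 to 79.6% on the other arms. The tests treat peaks as independent, which neighbouring peaks need not be.

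The fourth comparison asked which kinds of genes had promoter peaks. In 6 protein-coding lists they were more common than among other genes. Of 86 genes for cytoplasmic ribosomal proteins, 74 had a promoter peak, or 86.0% (interval 76.9 to 92.6%), against 25.9% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 6.59e-30 over 24 lists); RpS27, RpL7 (signal 717), RpL34b (703) and RpL28 (526) had the strongest. Of 33 chromatin and insulator regulators, 24 had one, or 72.7% (54.5 to 86.7%, exact adjusted p = 1.51e-07), led by ph-p, a Polycomb group gene (signal 475), the remodelling ATPase gene brm (458), and the insulator protein genes Cp190 (407) and BEAF-32 (278). The shares were 56.3% of 32 proteasome subunits (exact adjusted p = 0.000877), led by Rpn5 at 336, Rpn6 at 247 and Rpt5 at 216, and 54.8% of 73 mitochondrial ribosomal proteins (adjusted p = 1.13e-06), led by mRpL41, mRpS10 (890), mRpL23 (776) and mRpS23 (681). They were 50.9% of 53 translation factors (exact adjusted p = 0.000372), led by eIF6 at 1030, eIF1 at 526 and eIF4EHP at 414, and 52.4% of 21 Sm and splicing factors (adjusted p = 0.0206), led by SF2 at 296 and B52 at 169. RpL28 and eIF1 share the same peak. The call for Sm and splicing factors was lost among the 1947 strongest IDR peaks (exact adjusted p = 0.455) and with replicate 3 alone (adjusted p = 0.0567).

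Among non-coding genes, 7 of 32 spliceosomal snRNA genes had a promoter peak, or 21.9% (interval 9.28 to 39.97%), against 5.77% of other non-coding genes (Fisher's exact test, adjusted p = 0.00428). These included snRNA:7SKa (signal 171), which is not a spliceosomal RNA but a regulator of transcription elongation, a pair of U6 genes that share a peak at 170, and snRNA:U1:95Ca (157). The share of tRNA genes was 16 of 290, or 5.52% against 5.93% (exact adjusted p = 1), led by tRNA:Tyr-GTA-1-8 at 354 and tRNA:Phe-GAA-1-2 at 306.

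Chemosensory receptor, cuticle protein, digestive enzyme, homeotic and segmentation, testis and male accessory gland, neuronal and replication-dependent histone genes had promoter peaks less often than other protein-coding genes. Only 2 of 180 chemosensory receptor genes had one, Ir60e (signal 311) and Gr63a (99.6), or 1.11% (interval 0.135 to 3.96%, Fisher's exact test, adjusted p = 3.77e-20). The cuticle protein gene Lcp9 (128) was 1 of 85 (exact adjusted p = 1.30e-09), the maltase gene Mal-A5 (388) was 1 of 45 digestive enzymes (adjusted p = 8.97e-05), and bcd (109) was 1 of 31 homeotic and segmentation genes (adjusted p = 0.00353). None of 30 testis and male accessory gland genes had one (interval 0 to 11.6%, exact adjusted p = 0.000547). Of 28 neuronal genes, 2 had one, elav, an RNA-binding protein gene of neurons (534), and Syx1A (96.6), with an exact adjusted p = 0.0302; that call was lost among the 1947 strongest IDR peaks (adjusted p = 0.159), with a 250 bp promoter window (0.0937) and when TSSs within 1000 bp of each other were counted once (0.0973). None of 111 replication-dependent histone genes had one (exact adjusted p = 2.73e-14), but they lie in a repeated array on 2L, from 21416953 to 21541681, in which the pooled list held 0 candidates of any strength. How reads that match several copies were treated is not given in the sources used here, so peaks there may not have been detectable.

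The remaining 9 protein-coding lists did not pass the threshold. Oxidative phosphorylation genes had a promoter peak in 31 of 87, or 35.6% (Fisher's exact test, adjusted p = 0.0716), with COX6B and ND-24 strongest at 291, and DNA replication and cell cycle genes in 15 of 35, or 42.9% (adjusted p = 0.0532), with dpa at 435 and aurA at 326. Both lists passed in several alternatives: with replicate 3 alone (exact adjusted p = 0.0148 for oxidative phosphorylation and 0.000745 for replication and cell cycle, the latter with an odds ratio of 3.48 against 2.13), among the 1947 strongest IDR peaks (0.0304 for each), and with TSSs within 1000 bp of each other counted once (0.0126 and 0.0144). Oxidative phosphorylation also passed with a 1000 bp promoter window (exact adjusted p = 0.0347), and replication and cell cycle with a 250 bp window (0.0368). The counts were 12 of 40 germline and oogenesis genes, led by tral (440) and orb (191), 7 of 20 heat shock genes, led by Hsp83 (286) and Hsp27 (265), and 4 of 17 fat body and yolk genes, led by Lsd-2 (196) and FASN1 (157). They were 4 of 16 chorion and vitelline genes, led by Cp36 (146) and Cp7Fb (115.1), 3 of 24 muscle genes, Tm1 (96.6), Mef2 (94.6) and Actn (72.3), 1 of 20 antimicrobial peptides, Drsl6 (71.6), and 1 of 6 dosage compensation genes, msl-1 (156). The Tm1 peak rests on replicate 2 (signal 90.4). In replicate 3 it ranked 24225 with a signal of 7.47, near the weakest candidate at 6.69, and the Actn peak ranked 9301. Antimicrobial peptides passed as less often bound with replicate 3 alone (exact adjusted p = 0.00671) and with promoter windows of 250 bp (0.0229) and 1000 bp (0.0347), and muscle genes did among the 1947 strongest IDR peaks (0.0391). With so few members, wide intervals remain: that for heat shock genes runs from 15.4 to 59.2%.

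**Figure D4:**
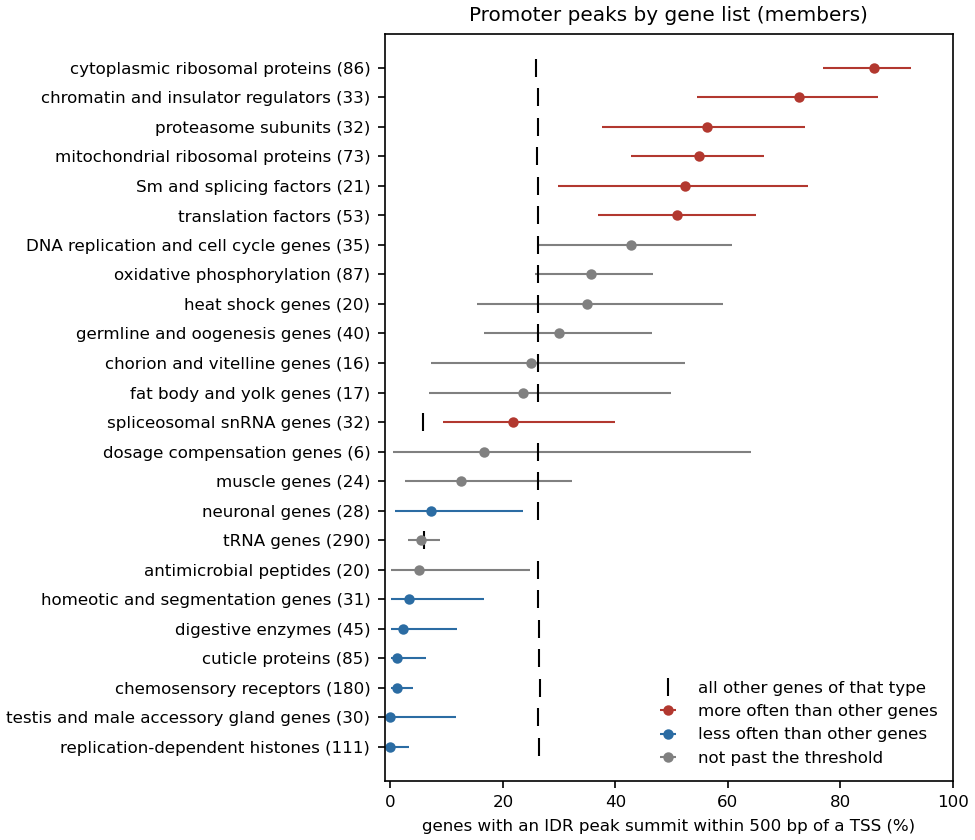
Share of genes with an IDR peak summit within 500 bp of a TSS (x axis, %) for each gene list (y axis, number of members in parentheses), with 95% exact binomial intervals as bars and the share of all other protein-coding or non-coding genes as black ticks. Red lists were above and blue lists below the other genes; cytoplasmic ribosomal proteins reached 86.0% and replication-dependent histones 0%.

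The fifth comparison asked which DNA motifs lay at the summits. Of 22 motifs, 8 were found within 50 bp of the summit in more peaks than in flanking windows of equal length centred 300 bp away, and 1 in fewer (exact McNemar test, two-sided, Benjamini-Hochberg adjusted). Several are core promoter elements of Drosophila. Motif 7 (CAKCNCTR) was found at 13.7% of summits and 4.29% of flanks (exact adjusted p = 4.95e-47), and the DNA replication-related element, DRE (TATCGATA), at 4.90% and 1.13% (adjusted p = 2.04e-22). Motif 1 (GGTCACACT) was found at 2.39% and 0.514% (exact adjusted p = 2.80e-12), motif 8 (GGCARCGSY) at 2.49% and 1.13% (adjusted p = 3.48e-05), and motif 6 (KTYRGTATWTTT) at 0.745% and 0.231% (adjusted p = 0.00456). The core of the CTCF insulator protein's motif (AGRKGGCGC) was at 93 summits and 11 flanks (exact adjusted p = 1.82e-16); with so few flanks its ratio of 8.13 (0.5 added to each count) was imprecise, and it was 12.4 with replicate 3 alone and 4.96 with a window of 100 bp either side. The E-box CAGCTG was at 7.32% of summits and 5.16% of flanks (exact adjusted p = 0.000306), and the MEF2 motif (CTAWWWWTAG) at 19 summits and 6 flanks (adjusted p = 0.0358). CA repeats were at 1.75% of summits and 5.03% of flanks (exact adjusted p = 2.02e-15). The TATA box (1.98% and 1.57%), the Initiator (9.04% and 9.48%) and the other 11 motifs did not pass.

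The motif calls differed in how well they held. DRE, CTCF, motif 1 and motif 7 passed with each replicate alone and in each other setting tried. With the strongest candidates of replicate 3 alone, 5 motifs passed, and motif 8 (exact adjusted p = 0.0865), the E-box CAGCTG (0.0527) and MEF2 (0.771) did not; MEF2 was not past the threshold with replicate 2 alone either (0.141). Among the 1947 strongest IDR peaks the E-box CAGCTG and motif 6 did not pass (exact adjusted p = 0.2005 for each), and with a window of 100 bp either side MEF2 did not (0.264). When 2883 promoter peaks were set against 5421 promoters of protein-coding genes with no candidate within 1000 bp, the share with motif 7 was 16.7% against 3.27%, with DRE 6.35% against 1.07%, and with motif 1 3.23% against 0.295%. In that comparison (Fisher's exact test) the Initiator was less frequent at the bound promoters, 8.98% against 17.2% (adjusted p = 7.40e-25), as was the TATA box, 2.01% against 5.44% (adjusted p = 3.61e-14), and MEF2 did not pass (0.555% against 0.646%). CA repeats, depleted against flanks, were not against unbound promoters (1.66% against 1.94%, exact adjusted p = 0.480). Some motifs passed only in alternatives. GAGA was less frequent at summits among the 1947 strongest IDR peaks (exact adjusted p = 0.00291), with replicate 3 alone (0.00516) and against unbound promoters (0.0113). Zelda was less frequent with a window of 100 bp either side (exact adjusted p = 0.0310) and against unbound promoters (0.00612), where GATA was too (0.000606) and E2F was more frequent (0.0269). Among the 1947 strongest IDR peaks Runt was less frequent (exact adjusted p = 0.00531) and the Su(Hw) core was at 11 summits and 1 flank (adjusted p = 0.0155), too few for a precise ratio; over all IDR peaks it was at 12 and 7 (adjusted p = 0.565).

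**Figure D5:**
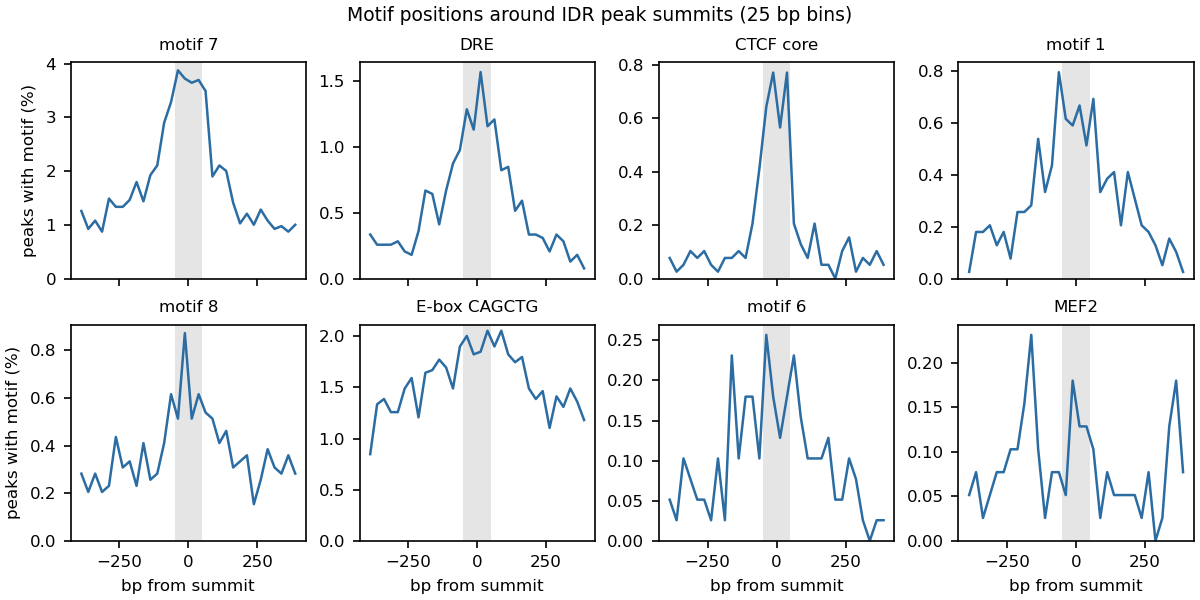
Share of the 3894 IDR peaks with a motif match (y axis, %, separate scales from 0) in 25 bp bins by distance from the summit (x axis, bp), for the 8 motifs found more often at summits than in flanks; the grey band is the 100 bp counted as the summit. Motif 7, DRE, motif 1 and CTCF rise to a maximum around the summit, whereas the MEF2 trace is as high at other positions.

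Without preset motifs, 302 of 2080 6-mers (reverse complements merged) were found at more summits than flanks and 407 at fewer. Among the 302, the lowest p-values belonged to CGATAG (12.2% of summits and 3.83% of flanks), TATCGA (15.4% and 6.01%), ATCGAT (12.2% and 4.39%) and ACACTG (12.5% and 4.73%). TATCGA and ATCGAT lie inside the DRE. Next among the 302 were ATATCG (9.55% and 4.08%), AACACT (11.8% and 5.75%), CAACAC (11.5% and 5.50%) and ACTATC (8.14% and 3.29%), and the A/T-rich AAATAT (27.9% and 18.7%) and ATTTTA (23.9% and 16.2%). Adjusted p-values ranged from 1.40e-41 to 1.23e-14 for these 10 (exact McNemar test). Of 287 6-mers more frequent at bound than at unbound promoters, 170 were among the 302. Of the 6-mers at fewer summits, CTCCTC had the lowest p, at 1.36% of summits and 5.24% of flanks. Summit windows held less G and C than flanks, a mean of 39.4% against 42.5% over all IDR peaks. The 6-mer test does not correct for this, so A/T-rich or G/C-rich 6-mers may reflect composition.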

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

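Replicate overlap, promoter share and the X share stayed past their thresholds and in the same direction in each alternative run for them, at 49.8 to 77.8%, 68.0 to 83.7% and 21.5 to 22.1% (20.1% for promoter peaks alone and 27.6% for other peaks alone, a split chosen after the data were seen). The correlation of the replicates ranged from 0.694 to 0.704. The median promoter peak exceeded other peaks by 11.02 and was no longer past the threshold among the 1947 strongest IDR peaks (permutation p = 0.0546); the cause was not tested, although fewer peaks entered. Between 14 and 16 of the 24 gene lists passed, and between 264 and 412 6-mers were more frequent at summits, against 302, of which 232 were shared with replicate 2 alone and 254 with replicate 3 alone. The number of motifs more frequent at summits ranged from 5 to 7 with 1 replicate left out, against 8, and the cause was not tested. Against unbound promoters the measure was an odds ratio between 2 sets of promoters, whereas the ratio against flanks compares windows of the same peaks. The 2 are therefore comparable in direction only. The TATA box had an odds ratio of 0.359, against a flank ratio of 1.26 that was not past the threshold (exact McNemar adjusted p = 0.341). MEF2 had an odds ratio of 0.873, not past the threshold, against a flank ratio of 3.00. The cause was not tested. Among single gene lists, motifs, named peaks and location classes, 267 values kept their side of the threshold or, without a test, stayed within the bounds set for them. Some of these, past the threshold in neither setting, changed direction. For dosage compensation genes the odds ratio was 0.766, against 1.47 among the 1947 strongest IDR peaks. A further 22 values moved past the threshold, 13 fell back from it and 14 without a test moved. Merging summits within 100 bp removed no peak, so that alternative tests nothing and is left out of these numbers. Read depth is unknown, and the candidate lists end at a rank, so absence from a list is not absence of binding.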

Other observations

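The tests of the CG1620 region, the odds ratios without cytoplasmic ribosomal proteins, and the comparisons in this first part, were chosen after the results were seen. Protein-coding genes whose first TSS faces that of a neighbour on the other strand within 1000 bp had a promoter peak in 2181 of 4562 cases, or 47.8% (95% exact binomial interval 46.3 to 49.3%), against 1481 of 9383 other protein-coding genes, or 15.8% (15.1 to 16.5%), an odds ratio of 4.89 (4.51 to 5.30). Counted by pair, 1214 of 2322 pairs, or 52.3%, had a peak at either gene; part of the difference follows from 2 genes sharing a peak. The X share was 20.1% of promoter peaks and 27.6% of other IDR peaks, an odds ratio of 1.52 (1.28 to 1.80; Fisher's exact test, two-sided, p = 2.06e-06).

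Motifs differed between promoter peaks and the 634 IDR peaks over 1000 bp from any TSS. The CTCF core motif was at 5.21% of the distant summits and 1.49% of promoter summits (Fisher's exact test, adjusted over 22 motifs, p = 8.83e-07). Motif 7 was at 5.05% of the distant and 16.4% of the promoter summits (exact adjusted p = 1.19e-14), DRE at 0.473% and 6.22% (adjusted p = 1.87e-11), and motif 1 at 0 of 634 and 93 of 2960 (adjusted p = 1.30e-07). Motif 1 was rarer among the strongest 973 IDR peaks, 0.822%, than among the weakest 973, 3.08% (exact adjusted p = 0.00917), whereas DRE was at 49 summits in each of these sets. G and C made up 36.7% of the summit windows of the strongest 973 peaks and 44.0% of their flanks, a mean difference over peaks of -7.33 percentage points (SE 0.450); for the weakest 973 peaks it was -0.602 points (SE 0.421).

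Cytoplasmic and mitochondrial ribosomal proteins, translation factors, proteasome subunits, splicing factors and chromatin regulators, 298 protein-coding genes in 6 lists, had promoter peaks more often than other protein-coding genes, with an odds ratio of 5.48 (4.30 to 6.97). The lists were pooled because each had been called in these peaks, so this ratio describes them and is no new test; without cytoplasmic ribosomal proteins it was 3.83 (2.91 to 5.04). If closely spaced TSSs, which let the peak of a neighbour count for a gene, were the whole cause, the difference should vanish among genes with equal numbers of own and neighbouring TSSs. It did not: the common odds ratio over such strata was 4.27 (3.29 to 5.55), or 3.08 (2.30 to 4.12) without cytoplasmic ribosomal proteins. Weak background at open promoters could also add peaks, and this stays open: of genes without an IDR peak, 2 of 98 in the lists and 492 of 9848 others carried one of the weakest candidates, an odds ratio of 0.396 with an interval of 0.0974 to 1.61. The design has no group that tests a biological explanation.

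The 9 IDR peaks within 20 kb either side of CG1620 could reflect extra copies of that region in the transgene, which should raise weak candidates as well. Weak candidates numbered 17, more than in 76.4% of windows around other protein-coding genes. This value lies between the bounds set for and against this explanation, which were written after results were seen. The region was not unusually rich in promoters: its 15 TSS positions exceeded those of only 65.7% of windows, against a median of 12. The bounds for this test too were written after results were seen, so the value is descriptive. Of 2009 windows with over 20% more TSS positions, 2.84% held as many IDR peaks. An earlier comparison used 5383 windows of a like number of TSS positions. Of these, 97.3% held fewer IDR peaks away from promoters and 99.18% held fewer IDR peaks of any kind. The latter is close to the 99.2% of all windows, so the number of promoters alone does not account for the excess in the region. That excess is a count of IDR peaks, several of which lay near the IDR cut-off. It was not tested among stronger peaks alone. Whether the promoters of the region are more active than others was not tested. IDR peaks were as common 20 to 40 kb away, at 10, as within 20 kb, and 0 lay from 40 to 60 kb. In 10 kb bins the pooled list held 3 to 11 candidates of any strength within 40 kb and 1 to 3 beyond. Replicate 2 gave the same ranges, and replicate 3 gave 4 to 7 and 1 to 2. Extra copies of a bounded region could give such a drop, but no comparison with other regions is given here for these bins. Extra copies, and regulation of the gene and its neighbours by its own product, stay open, since neither transgene size nor control coverage was analysed here.

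The 7-mer AACCCCC was found within 50 bp of 8 of the 400 strongest summits, or 2.00% (interval 0.867 to 3.90%), which had drawn attention in a search of many 7-mers. In the next 600 peaks, down to rank 1000, which that search did not use, it was at 2 summits, or 0.333%, against 20 of 2894 later peaks, or 0.691% (Fisher's exact test, two-sided, p = 0.407). The excess at the strongest summits is therefore consistent with a chance find, although a motif confined to the very strongest peaks would escape this test.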
